A study of Mus musculus with 6 samples.

How the data were processed

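RNA-seq was made from mouse uterine luminal epithelium, the cell layer that lines the uterine cavity and meets the embryo, isolated by laser capture on pregnancy day 4. The 6 samples formed 2 groups of 3, read from the titles and genotype labels: females with floxed Foxo1 alleles and no Cre (Foxo1ff), and females that also carried 1 copy of a Cre gene inserted at Pgr, the progesterone receptor gene (Foxo1dd). The labels call the samples of a group bioreplicates and say nothing more of the animals behind each, so p-values measure the spread between these samples. All 6 libraries carry the same run and lane label.

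The deposited table holds 1 FPKM value (an expression level divided by gene length and by library depth) for each of 24964 genes in each sample, computed by the authors before deposit. Per the submitters' processing notes, genome build mm10, STAR 2.5.2b, featureCounts 1.5.0-p1 from Subread, edgeR 3.28.0 and DESeq2 1.12.4 were named, with no role or order. The annotation, the gene lengths, the strand setting, the treatment of reads with several matches and any further scaling between libraries are not given in the sources used here. Without strand, reads of a gene and of an antisense neighbour cannot be told apart, and near-identical genes can exchange reads. Gene symbols were used as deposited, and 24423 of them have the same symbol in GENCODE M21, an annotation of GRCm38, the assembly that mm10 names. Positions of the 145 genes looked up come from that annotation. In it, Fgfr2, Pik3r3, Slpi, Col3a1, Egfl7, Top2a and Ctsd, all named below, overlap exons of other genes on the same strand. Their values are uncertain for that reason.

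FPKM values are not counts, so no count model was used. Depth was read from the low values of microRNA and small nucleolar RNA genes, whose FPKM multiplied by length stepped in whole multiples of what 1 read is worth. The step taken was the largest at which at least 80% of values below 12 reads were whole to within 0.05 of a read, a limit set after the values had been seen. The share of whole values was 88.5% to 100% per library, over 26 (Foxo1dd 2) to 131 such genes. By this step, 1 read was worth 0.0101 to 0.0135 FPKM for a gene of 1 kb, which is a divisor of about 74000000 to 98600000 reads if no other factor entered. The low end is Foxo1dd 2, whose value turns on that limit. A limit of 90%, tried before it, gave this library a step of 0.00676 FPKM over 16 genes and a divisor of 148000000 reads, and left the other 5 libraries as they were. The larger step was kept because 5 of its values lie at 0.0135 FPKM and 0 below 0.75 of that, so its depth is the least certain. Lengths are from the RefSeq annotation of the same assembly. At the steps kept, for a 2 kb gene 1 read equals about 0.00507 to 0.00676 FPKM, so the minimum used below stands well above the value of a single read.

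Each gene was tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with genotype as the only term. Genes with a mean of at least 1 FPKM over the 6 samples were tested, which kept 11427 and left out 13537. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are Foxo1dd minus Foxo1ff on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their limma standard error. Folds are ratios of group means of FPKM. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so no such test was used for single genes.

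In all, 37 gene lists were fixed before the data were examined, covering pathways, RNA quality and cell types that a captured strip could hold. The 29 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and p-values were adjusted over those lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in a single direction without comparing them with other genes, were alternatives. The test, the filter, the pseudocount, the lists, the alternatives and the rule for named genes were chosen before the data were examined. That rule takes Foxo1, Pgr and the other FOXO genes. It adds the 12 largest rises and 12 largest falls among called genes whose 3 Foxo1dd values all lie outside the Foxo1ff range, leaving out, by their symbols alone, unnamed gene models and pseudogenes (-ps). The symbol rule kept Sprr2g, which GENCODE types as a polymorphic pseudogene. It also adds up to 4 tested members of each list with the smallest p. Any other gene named was chosen after its values had been seen.

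The alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, eBayes without a trend or with robust settings, array weights, the bioreplicate number as a replicate block, the other set tests, and leaving out each sample in turn. The procedure was tested on simulated data for the Foxo1dd against Foxo1ff comparison, with 200 of 11427 genes changed. It called 10% of genes changed by 0.5 log2, 52% of those changed by 1, 94% of those changed by 2 and 94% of those changed by 4. It called 5 unchanged genes, 3.85% of its calls, and gave 0 calls of the wrong sign. With so few genes changed, its adjusted threshold was stricter than in the data, where 56.4% of tested genes were called. The shares recovered are therefore not the sensitivity of the real comparison. Camera called the 1 shifted list and 0 of 28 others. The simulated genes varied independently of each other, so this does not test camera where the genes of a list vary together. In the data the estimated inter-gene correlation was 0.71 for proliferation genes and 0.52 for interferon-stimulated genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for annotation, further tests and plots.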

Results

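The comparison asked how the luminal epithelium differs on pregnancy day 4 when Foxo1, a forkhead transcription factor acting downstream of insulin signalling, is deleted in cells that express the progesterone receptor. The wider series is about what the forms of the progesterone receptor do in the uterine epithelium when embryos implant. Expression was measured by RNA-seq in 3 Foxo1ff and 3 Foxo1dd samples of laser-captured epithelium. Summed FPKM per sample ran from 613186 to 667499 in Foxo1ff and from 552190 to 564628 in Foxo1dd. Genes above 0 numbered 13995 in Foxo1dd 2 and between 15474 and 16062 in the other 5 samples. Foxo1dd 2 also had the highest value of the ribosomal RNA precursor Rn45s, 40296 FPKM against 23715 to 31304 in the others, and values above 0 for 94 short RNA genes against 172 to 232. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.969 to 0.990 within groups and 0.766 to 0.813 between them.

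Foxo1 (chromosome 3, 52268336 to 52353221, plus strand, mm10) was 100.2-fold lower in the Foxo1dd samples. Its FPKM was 160.0, 118.5 and 110.8 in Foxo1ff and 1.72, 0.942 and 1.22 in Foxo1dd, a log2 change of -5.83 ± 0.19 (SE, n = 3 per group, limma adjusted p = 1.21e-07). Pgr (chromosome 9, 8899833 to 8968611, plus strand), the locus that holds the Cre insertion, moved the other way. It rose from 2.44, 1.64 and 2.02 FPKM to 36.2, 29.9 and 28.3 FPKM, a log2 change of 3.42 ± 0.16 (SE, n = 3 per group, adjusted p = 7.45e-07). Values are per gene, so neither the floxed exon nor reads from the insertion were resolved, and the annotation places exons of Gm20402 antisense to Foxo1. The related factors Foxo3 and Foxo4 were not called (adjusted p = 0.384 and 0.617), with 7.04 and 14.3 FPKM in Foxo1ff and 5.67 and 13.3 FPKM in Foxo1dd. The sign of the Foxo4 change (-0.13) turned under median-of-ratios scaling (0.02). Foxo6 lay below the minimum, at 0.200 and 0.0733 FPKM. Of the 3 tested FOXO family genes, 0 rose and 1 fell, over all genes and adjusted over the list alone.

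Among the 12 largest falls, Prap1, a secreted proline-rich protein that on chromosome 7 (140093395 to 140097200) overlaps exons of Fuom on the opposite strand, had a mean of 10074 ± 2866 FPKM in Foxo1ff and 24.4 ± 18.4 FPKM in Foxo1dd (SD, n = 3 each). Igfbp3, an insulin-like growth factor binding protein, had 6218 ± 445 against 19.9 ± 9.13 FPKM, and Depp1, a known FOXO-induced gene, 1326 ± 225 against 1.62 ± 1.13 FPKM (SD, n = 3 each). Their log2 changes were -9.12 ± 0.73, -8.33 ± 0.32 and -9.05 ± 0.26 (SE). The others were Mmp7 (matrilysin), Gpx3 (a secreted glutathione peroxidase), Rnase1, Atp6v0d2 (a proton pump subunit), Olfm1, Ttpa (a vitamin E transfer protein), Pinlyp, Rnase4 and Gabrp, with log2 changes from -8.32 for Mmp7 to -6.35 for Gabrp. Rnase4 shares exons with Ang on the same strand, and Mmp7 lies opposite exons of AV064505, so their values are uncertain. Mmp7 also lies 1.21 Mb from Pgr, on the chromosome that carries the Cre insertion.

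Among the 12 largest rises, Fxyd4, a regulator of the sodium pump (chromosome 6, 117933559 to 117937692, minus strand), went from 5.58 ± 6.83 to 1647 ± 410 FPKM, and Alox15, a lipoxygenase, from 4.07 ± 3.17 to 1161 ± 242 FPKM (SD, n = 3 each). Plekhs1 rose from 3.82 ± 3.81 to 1012 ± 90.0 FPKM and Il17rb, an interleukin receptor subunit, from 11.8 ± 5.74 to 1062 ± 226 FPKM (SD, n = 3 each). The log2 changes of Fxyd4, Plekhs1, Alox15 and Il17rb were 8.49 ± 0.62, 8.17 ± 0.61, 8.00 ± 0.37 and 6.45 ± 0.29 (SE). The remaining rises were Sprr2f (6.93), Slc2a3, a glucose transporter (6.89), Calb1, a calcium-binding protein (6.75), Slc13a5, a citrate transporter (6.70), Thrsp, a gene tied to fat synthesis (6.65), AU021092 (6.41), Sprr2g (6.37) and Rasd1 (6.36), as log2 changes. Sprr2f and Sprr2g, the latter annotated as a polymorphic pseudogene, belong to a family of near-identical genes and their split is uncertain. Slc13a5 and Il17rb overlap antisense exons of 1700051A21Rik and Actr8. Limma adjusted p of the 24 genes ran from 1.09e-07 for Depp1 to 1.08e-05 for Sprr2g. By the rule that chose them, all 3 Foxo1dd values of each gene lie beyond the Foxo1ff range.

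**Figure D1:**
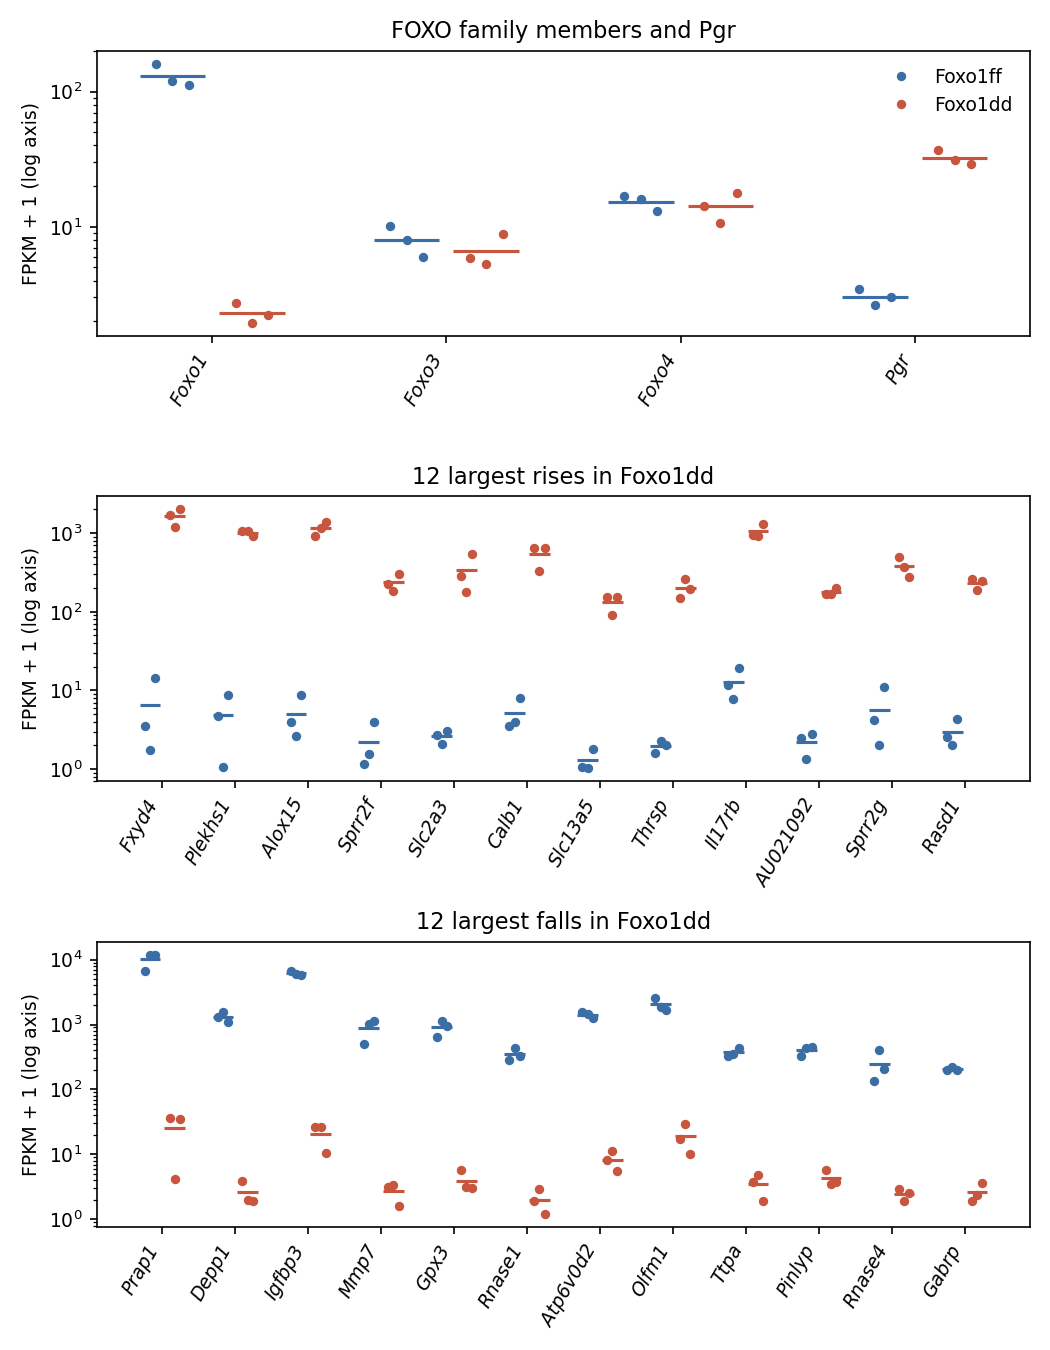
FPKM + 1 on a log axis for FOXO family members and Pgr, the 12 largest rises and the 12 largest falls; each point is a sample (3 Foxo1ff, blue; 3 Foxo1dd, red) and each bar the mean of FPKM, plus 1. Foxo1 lies between 110.8 and 160.0 FPKM in Foxo1ff and at or below 1.72 FPKM in Foxo1dd.

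Most tested genes differed between the genotypes. Of 11427 genes tested, 2533 were higher and 3912 lower in Foxo1dd, together 56.4%. A change of at least 1 log2 was seen in 1273 of the higher and 1807 of the lower genes, and of at least 2 log2 in 455 and 578. The samples of the groups did not overlap for 2890 genes higher and 4451 lower, 64.2% of those tested, against 10% by chance. The median log2 change of all tested genes was -0.15, and median-of-ratios scaling shifted it by 0.14, to -0.01. Under that scaling 3184 genes were higher and 3301 lower, so the higher share of calls went from 39.3% to 49.1%, and under quantile normalization it was 49.1% as well (3236 higher, 3360 lower). The same direction was called under both the deposited and the median-of-ratios scale for 5834 genes, and opposite directions for 0. Small falls are therefore to be read against the median of -0.15.

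**Figure D2:**
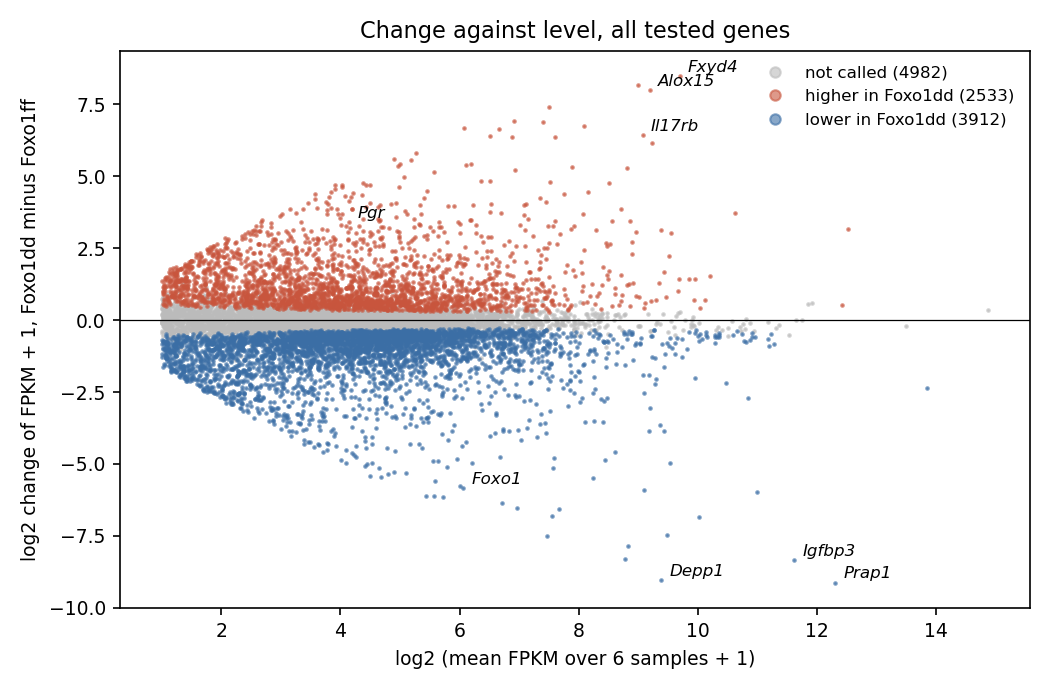
Log2 change of FPKM + 1 (Foxo1dd minus Foxo1ff) against the log2 mean FPKM + 1 over the 6 samples, each point a tested gene: red, higher in Foxo1dd (2533); blue, lower (3912); grey, not called. Called genes lie across the whole range of levels.

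Cell-cycle genes were lower together. Of 40 proliferation genes, 0 rose and 39 fell, over all genes and adjusted over the list alone, with a median log2 change of -2.79. Mcm6 and Mcm5, subunits of the replicative helicase, had 51.4 ± 7.84 and 33.1 ± 5.95 FPKM in Foxo1ff and 1.46 ± 0.608 and 1.62 ± 0.491 FPKM in Foxo1dd, and Uhrf1 and E2f1 were 22.8-fold and 78.8-fold lower (SD, n = 3 each). Ccnd1, the cyclin D1 gene of the estrogen-responsive list, was 119 ± 8.57 against 3.35 ± 1.31 FPKM. The gene outside the calls, named after its values were seen, was Top2a, at 20.5, 45.6 and 29.9 FPKM in Foxo1ff and 27.1, 20.3 and 61.4 FPKM in Foxo1dd. Top2a overlaps exons of Gm23451 on the same strand, so its value is uncertain. Camera placed the list below other genes at adjusted p = 2.14e-12, and at adjusted p = 0.901 with an estimated correlation. Beside this, 9 of 15 leukocyte markers fell and 2 rose, Ptprc from 3.59 to 0.294 FPKM.

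Interferon-stimulated genes were higher. Of 31 tested, 24 rose and 3 fell, over all genes and adjusted over the list alone (median log2 change 2.00). Irf7, a transcription factor of the interferon response, went from 2.20 ± 1.30 to 134 ± 56.7 FPKM, Isg15 from 1.35 ± 0.287 to 91.4 ± 45.6, Xaf1 from 2.71 ± 0.786 to 82.5 ± 13.2 and Usp18 from 0.462 ± 0.153 to 40.7 ± 18.5 (SD, n = 3 each). The 3 that fell, named after their values were seen, were Ifit3b, Ifit3 and Ifit2, with log2 changes of -3.23, -2.36 and -0.80. Ifit3 and Ifit3b share much of their sequence and their split is uncertain. The camera adjusted p was 1.80e-09, and adjusted p = 0.901 with an estimated correlation. Beside this, only 3 of 16 neutrophil markers reached the minimum of 1 FPKM, and these 3 rose. They were Hdc, from 134 to 1191 FPKM, Ltf, from 14.2 to 138 FPKM, and Ly6g, from 0.120 to 2.45 FPKM. Ltf is also on the estrogen-responsive and antimicrobial lists. With most of the list below the minimum, these rises do not show a neutrophil signal. Of 15 leukocyte markers 2 rose, Laptm5 15.7-fold and Cd68 from 4.73 to 7.50 FPKM, and 9 fell.

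Regulators of implantation and progesterone-responsive genes were mostly higher. Of 25 implantation regulators, 15 rose and 4 fell (the same numbers adjusted over the list alone), with Lpar3, a lysophosphatidic acid receptor, at 5.20 ± 1.47 against 175 ± 11.7 FPKM, and Sox17, Msx1 and Pla2g4a 5.82-fold, 5.34-fold and 3.57-fold higher (SD, n = 3 each; camera adjusted p = 0.00711, and adjusted p = 0.901 with an estimated correlation). Of 17 progesterone-responsive genes, 10 rose and 3 fell (the same adjusted over the list alone), at camera adjusted p = 0.0298 and adjusted p = 0.901 with an estimated correlation. Members with the smallest p went both ways: Lrp2, an endocytic receptor, and Bhlhe40 had log2 changes of 3.96 and 2.82, while Cyp26a1, which degrades retinoic acid, and Sgk1, a kinase acting on ion channels, had -2.20 and -4.24. Ihh, a hedgehog ligand, had 70.4 and 82.0 FPKM and was not called. This list lost its call without a filter (adjusted p = 0.238), under quantile normalization (0.0539), with fry (0.0541) and without Foxo1dd replicate 3 (0.0520), over a range of 0.0137 to 0.901 among its alternatives. Of 14 steroid receptors and cofactors, 5 rose and 1 fell, with Gata2 and Pgrmc2 4.65-fold and 2.43-fold higher, and the list missed the threshold (camera adjusted p = 0.0531). The largest rise of the list was that of Pgr itself (3.42 log2), the locus of the Cre insertion, whose reads were not resolved. The list was not tested without Pgr. Under median-of-ratios scaling 7 rose and 1 fell and the list passed (camera adjusted p = 0.0479), while on the deposited scale it had adjusted p = 0.901 with an estimated correlation. The gene that fell was Ncoa3 (log2 change -0.63, adjusted p = 0.0197), whose call was lost without a filter (0.0501) and without Foxo1ff replicate 1 (0.0735), Foxo1ff replicate 2 (0.0680) or Foxo1dd replicate 1 (0.0549).

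Of 11 Notch pathway genes, 7 rose and 0 fell (the same adjusted over the list alone), at camera adjusted p = 0.00366 and adjusted p = 0.901 with an estimated correlation. Nrarp, Notch1, Hes1 and Jag2 were 13.1-fold, 5.10-fold, 2.74-fold and 3.94-fold higher. FOXO target genes did not pass camera (adjusted p = 0.134): of 26, 4 rose and 13 fell, with Igfbp1 at 19.0 ± 3.05 against 0.0107 ± 0.00929 FPKM and Eif4ebp1 at 195 ± 28.8 against 6.17 ± 0.928 FPKM (SD, n = 3 each). Fry, which does not compare a list with other genes, gave adjusted p = 0.00987 for a fall. Of 19 estrogen-responsive genes, 9 rose and 7 fell, with Aqp8, a water channel, at 25.4 against 0.314 FPKM. Pgr, which holds the Cre insertion, is among the 9 that rose.

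The remaining signalling lists moved in both directions and none passed camera, while fry passed the insulin and IGF list (adjusted p = 0.0346, down) and the prostaglandin list (adjusted p = 0.00987, up). Of 23 WNT genes, 11 rose and 8 fell, Wnt7b going from 590 ± 78.9 to 12.2 ± 1.88 FPKM and Ror2 from 4.38 ± 0.0907 to 31.7 ± 3.21 FPKM (SD, n = 3 each). Of 19 FGF and EGF genes, 4 rose and 5 fell (6 and 3 under median-of-ratios scaling), with Fgf9 39.0-fold lower and Fgf18 and Fgfr2 higher by 4.69 and 1.41 log2. Of 16 hedgehog and BMP genes, 2 rose (Id2 and Acvr1) and 6 fell, including Id1 and Id4. Of 21 insulin and IGF genes, 6 rose and 11 fell, with Pik3r3 8.95-fold higher. Of 20 prostaglandin genes, 11 rose and 6 fell, with Hpgds 4.08-fold lower and Pla2g10 higher by 2.99 log2. Of 25 apoptosis regulators, 9 rose and 9 fell, Casp1 3.21-fold higher and Bid 4.90-fold lower. Casp1 lies within 5 Mb of Pgr, on the chromosome that carries the Cre insertion.

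Among transport and metabolic lists, 11 of 23 ion and water transport genes rose and 8 fell, with Scnn1b, a sodium channel subunit, 62.9-fold lower and Slc12a2, a chloride importer, 3.52-fold lower. Of 23 glucose and glycogen genes, 8 rose and 11 fell (8 and 9 under median-of-ratios scaling), with Slc2a1 5.21-fold lower and Pfkfb3 higher by 3.24 log2. Of 26 cholesterol and fatty acid genes, 6 rose and 13 fell (6 and 10 under that scaling), with Fasn 3.75-fold higher and Hmgcs1 3.08-fold lower. Of 28 oxidative stress genes, 12 rose and 9 fell (13 and 5 under that scaling), Nqo1 23.6-fold higher, Gstm1 and Gstm2 higher as a pair of similar genes whose split is uncertain, and fry gave this list adjusted p = 0.0419 for a rise. Of 22 matrix remodelling genes, 10 rose and 9 fell, with Lama3 16.1-fold lower and Itgb6 12.8-fold higher. Of 38 junction and polarity genes, 5 rose and 15 fell, but 11 and 11 under median-of-ratios scaling, with Tjp3 and Cldn23 3.16-fold and 1.95-fold higher. Of 14 mucin and glycocalyx genes, 3 rose and 8 fell, Fut2 20.1-fold and Muc1 2.80-fold higher. Of 15 antimicrobial genes, 7 rose and 6 fell, Cxcl17 higher by 1.71 log2 and Slpi at 17.0 against 0.103 FPKM. None of these lists passed camera, which placed the junction, glucose, matrix, antimicrobial, FGF and EGF, hedgehog and BMP, apoptosis, immediate early, glandular and smooth muscle lists above other genes although their median or mean change was negative.

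Markers of the capture and of RNA quality were measured alongside. Of 22 luminal and pan-epithelial markers, 8 rose and 6 fell (11 and 5 under median-of-ratios scaling), with Elf3 3.89-fold higher and Spint1 4.26-fold lower. Of 8 glandular markers, 4 rose and 4 fell, Spink1 from 93.3 ± 74.0 to 0.124 ± 0.162 FPKM (SD, n = 3 each). Of 14 stroma markers, 3 rose over all genes (Sparc, Col3a1 and Nr2f2) and 0 adjusted over the list alone. The call of Col3a1 was lost without a filter (adjusted p = 0.0586) and without Foxo1ff replicate 1 (0.0550), Foxo1ff replicate 2 (0.0853), Foxo1dd replicate 1 (0.0652) or Foxo1dd replicate 3 (0.0731). That of Sparc was lost without Foxo1ff replicate 1 (0.0542), Foxo1ff replicate 3 (0.0792) or Foxo1dd replicate 1 (0.0616). That of Nr2f2 was lost on leaving out any of the samples other than Foxo1dd replicate 2 (0.0733 to 0.110). Of 6 smooth muscle markers, 2 rose (Synpo2 and Myl9) and 1 fell (Smtn). Of 15 leukocyte markers, 9 fell and 2 rose, C1qa 4.68-fold lower and Laptm5 15.7-fold higher.

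Lists with under 5 tested members were not tested as lists. Of 18 endothelial markers 2 reached the minimum, of which Sox7 rose and Egfl7 fell. Of 16 neutrophil markers 3 reached it, Hdc, Ltf and Ly6g, and these rose. Of 2 mesothelium markers Krt5 rose and Msln fell, from 32.2 ± 5.98 to 0.0443 ± 0.0450 FPKM (SD, n = 3 each). The ciliated cell marker Tppp3 rose, as did the trophoblast list's Elf5 and Krt8, the latter also an epithelial keratin. No erythroid marker reached the minimum, Hba-a1, Hba-a2, Hbb-bs and Hbb-bt being listed at 0 in every sample, and no mitochondrially encoded gene was in the table under the symbols searched. Of 36 ribosomal protein genes, 1 rose (Rps27) and 17 fell, with 1 and 6 under median-of-ratios scaling (camera adjusted p = 0.0531). Of 19 immediate early and heat-shock genes, 5 rose and 7 fell, with 7 and 5 under that scaling. Adjusted over the list alone, counts differed from those over all genes for WNT genes (12 rose), FGF and EGF genes (4 fell) and stroma markers (0 rose), and for no other list.

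**Figure D3:**
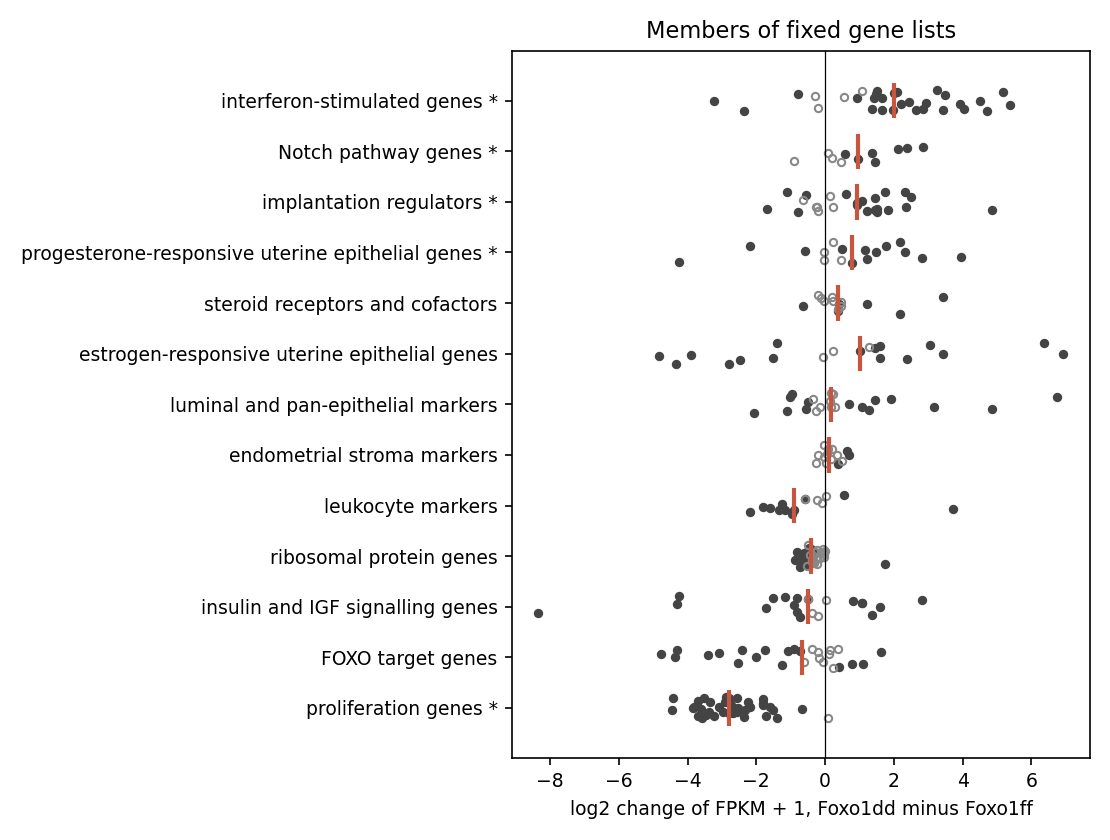
Log2 change of FPKM + 1 (Foxo1dd minus Foxo1ff) of the tested members of 13 fixed lists; filled points passed limma's adjusted threshold, open points did not, red bars are list medians and asterisks mark lists past camera's threshold at the preset correlation. Of 40 proliferation genes 39 lie below 0 and passed, and 24 of 31 interferon-stimulated genes lie above 0 and passed.

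In all, 5 of 29 tested lists passed camera at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.901). The groups hold 3 samples each, and the genotypes differ in the Pgr allele as well as in Foxo1.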

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

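All alternatives here were planned. The counts of higher and lower genes and the Foxo1 and Pgr changes kept their direction and their side of the threshold, or stayed within 1.5 times, under every alternative run. Leaving out each sample in turn gave 2134 to 2714 genes higher and 3050 to 3751 lower, Foxo1 changes of -5.96 to -5.67 and Pgr changes of 3.32 to 3.52. Other alternatives gave 1962 (mean of at least 5 FPKM) to 3236 genes higher (quantile normalization) and 3153 to 4424 lower (mean of at least 5 FPKM, array weights). The number of lists past the threshold moved from 5 to 8 with the replicate block, 0 for camera with an estimated correlation and 8 for fry, and was 4 to 7 on leaving out samples; fry asks another question, and the cause of the other changes was not tested. Same-numbered samples of the groups deviated together no more than others (correlations 0.12, 0.11 and -0.13, against -0.21 to 0.15). This gives no sign that the numbers pair the samples, and 3 samples per group are too few to exclude it. The replicate block gave 2417 genes higher and 3724 lower, and among named genes it ended the call of Nr2f2 (limma adjusted p = 0.0712). Of the 138 named genes, those other than Foxo1 and Pgr had 2154 values under alternatives. Of these values, 2132 kept direction and call, 18 lost the call, 2 gained it and 2 changed sign. The sign changes were those of Foxo4, which was never called: its change was 0.015 under median-of-ratios scaling, and on leaving out samples ran from -0.31 without Foxo1dd replicate 3 to 0.068 without Foxo1dd replicate 2, and the cause was not tested. None of the 24 genes with the largest rises and falls changed call. With 3 samples per group, simulated changes of 0.5 log2 were called for 10% of genes. That simulation changed 200 of 11427 genes, against 6445 called in the data, which made its adjusted threshold stricter. Its 10% is therefore not the sensitivity here, and F11r, for example, was called at 0.48 log2. Small changes can still be missed.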

Other observations

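The lists of the opening paragraphs and all tests below were chosen after the results had been seen, except the sequence-word test of Ifit1, whose limits were set before its value was known. Genes of the secretory pathway and of ribosome assembly were lower in Foxo1dd. Of 54 genes of the endoplasmic reticulum secretory pathway, 1 rose and 47 fell (3 and 45 under median-of-ratios scaling), with Xbp1, a transcription factor of secretory cells, at 1044 ± 64.4 FPKM in Foxo1ff and 126 ± 5.97 FPKM in Foxo1dd, and Hspa5, the main chaperone of that compartment, at 1026 ± 329 against 219 ± 58.1 FPKM (SD, n = 3 each). Of 54 ribosome biogenesis genes, 2 rose and 51 fell (2 and 44 under that scaling), with Myc at 105 ± 29.9 against 5.33 ± 3.02 FPKM and Nop56 at 118 ± 6.67 against 35.7 ± 7.10 FPKM (SD, n = 3 each). Camera gave adjusted p = 3.15e-10 and 3.97e-09 for these lists, and adjusted p = 0.314 for each with an estimated correlation. Camera p-values of these lists and of the keratin, calcium and lysosomal lists below were adjusted only among themselves. The lists were chosen from the same values, so these p-values describe them and do not test them. Beside these falls, 17 of 36 ribosomal protein genes fell (6 under median-of-ratios scaling), as did 9 of 15 leukocyte markers (8 under that scaling).

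Of 12 keratins, 8 rose and 1 fell, Krt80 (9 and 1 under median-of-ratios scaling), with Krt19 at 47.8 ± 21.4 against 417 ± 136 FPKM (SD, n = 3 each; camera adjusted p = 8.66e-04, and adjusted p = 0.314 with an estimated correlation). Genes of calcium transport went in both directions, 3 up and 6 down of 10, and camera gave adjusted p = 0.471. The calcium-binding protein genes S100g and Calb1 moved oppositely, S100g from 24609 ± 3407 to 4898 ± 1465 FPKM and Calb1 from 4.13 ± 2.43 to 539 ± 182 FPKM, while the calcium channel gene Trpv6 went from 668 ± 118 to 22.4 ± 7.71 FPKM (SD, n = 3 each). Of 44 lysosomal genes, 10 rose and 22 fell (camera adjusted p = 0.457), and Ctsd, a lysosomal protease, rose from 1190.5 ± 138 to 10593 ± 1239 FPKM (SD, n = 3 each). Ctsd overlaps exons of Gm49369 on the same strand, so its value is uncertain. Of 133 families of at least 10 tested genes that share a symbol stem, 2 passed camera's threshold at the preset correlation. An estimated correlation was not tried for them, so these calls are unsettled.

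More than 50% of tested genes differed between the genotypes, and 90.5% of them were called in the same direction under median-of-ratios scaling. That scaling applies 1 factor per library, so this argues only against such a factor as their source. A scaling by the authors that differs between genes was not tested. Stromal RNA would have to shift its markers by about the 0.96 log2 typical of called genes. The 14 stroma markers tested, of 25 listed, had a median of 0.12 (SD 0.29), with 3 called higher and 0 lower. Most changes of low genes are shrunk by the pseudocount. Sparc and Col3a1, 1.91-fold and 1.87-fold higher in FPKM, had log2 changes of 0.64 and 0.70. The size of the marker changes therefore cannot settle how much stromal RNA contributed. Sequence carried along with the Pgr allele that holds Cre would concentrate the calls nearby. Both groups are labelled with floxed Foxo1, so sequence carried with that allele would not differ between them by label. Of the 40 tested genes within 5 Mb of Foxo1 or Pgr, 57.5% were called (exact 95% interval 40.9% to 73.0%), against 56.6% of 11254 others. By locus, 12 of 21 near Pgr and 11 of 19 near Foxo1 were called. With calls so common elsewhere, this bears on the bulk of the calls and not on the nearby genes. For those near Pgr, carried-along sequence stays open. They include Mmp7 (log2 change -8.32, 1.21 Mb from Pgr) and Casp1 (1.64). Besides Mmp7, the nearby gene with a change beyond 2 log2 was Maml3 (-3.56), which lies near Foxo1. The real split called 6445 genes and the highest of the 9 others 0; 1 of 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. The Foxo1 deletion, the Pgr allele that carries Cre and the hour or stage of pregnancy at collection remain open, untested, since the first pair came together in every Foxo1dd sample and no label gives the hour.

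The lower proliferation genes in Foxo1dd could reflect other dividing cells captured with the Foxo1ff epithelium. Proliferating stroma would lower its markers along with the list, which fell by 2.79 log2 at the median. The stroma markers had a median change of 0.12 (SD 0.29), and 0 of 14 were called lower. The highest mean level among them was 28.9 FPKM (Nr2f2). Markers as low as Sparc, Col3a1 and Hoxa11 (1.56, 2.86 and 1.46 FPKM in Foxo1ff) cannot fall by 2.79 log2 on this scale. Only the direction of their change therefore bears on this explanation, not its size. Leukocytes would bring their abundant transcripts, yet the 15 leukocyte markers fell by a median of 2.39 FPKM (upper quartile 3.63) against 12.1 FPKM (lower quartile 7.30) for the proliferation genes. This assumes that leukocytes hold more of these markers than of cell-cycle transcripts, which was not tested. As ratios the markers could fall far, Ptprc by 12.2-fold, with 9 of the 15 called lower and 2 higher. If the assumption fails, the comparison in FPKM cannot set leukocytes aside. Top2a, a proliferation gene, had 32.0 ± 12.7 FPKM in Foxo1ff and 36.3 ± 22.1 FPKM in Foxo1dd (SD, n = 3 each) and was not called (limma adjusted p = 0.862). Its overlap with Gm23451 on the same strand leaves that value uncertain. No test here bears on the rate of division itself, and genotype and the stage of pregnancy at collection stay open, untested.

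Interferon-stimulated genes were higher, Ifit1 by 4.03 ± 0.37 log2 (SE), while Ifit2, Ifit3 and Ifit3b were lower, as was Ifit1bl1 (7.38 ± 3.33 against 0.443 ± 0.543 FPKM; SD, n = 3 each). Reads moved between Ifit3 and Ifit3b, which share 58.5% of the 36-base words of Ifit3 transcripts, would leave their sum in place, yet log2 of the sum plus 1 was lower by 3.18 ± 0.76 (SE) in Foxo1dd and both genes fell. Of the 2620 words of Ifit1 transcripts 3.89% occur in the other genes, between the limits of 1% and 10% set beforehand, all of them in Ifit1bl1 and 0 in Ifit2, Ifit3 or Ifit3b. All reads of Ifit1bl1 in its highest Foxo1ff library would give Ifit1 8.995 FPKM. That lies below the 23.7 FPKM between the lowest Foxo1dd and highest Foxo1ff values of Ifit1. If Ifit1bl1 gave no more reads in Foxo1dd than in that library, reads moved from it cannot make the whole rise. Under that assumption, which was not tested, only a smaller share of the rise stays open. No biological explanation of the split was tested.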
